A study of Homo sapiens with 9 samples.

How the data were processed

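Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and tags it for sequencing, in MCF-7 cells, a human breast cancer line that carries the estrogen receptor. Per the labels' protocols, cells were kept in medium without hormones for 4 to 5 days, treated for 45 min with the solvent DMSO, with 1 nM estradiol (E2) or with 100 nM fulvestrant (FULV), and processed as 100000 cells per condition with 30 min of tagmentation, 10 cycles of PCR and paired reads of 38 bp. Each group held 3 libraries. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical.

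The authors deposited a table of raw counts, whole numbers per region and library with no normalization, over 123459 regions of 150 to 2088 bp (median 373 bp) on 23 chromosomes. Per the submitters' processing notes the genome build was hg38 and the tools were Trimmomatic, Bowtie2, Picard, SAMtools and MACS3, named there without role, order or version. The program that made the counts was not given in the sources used here. The authors also deposited a peak list per condition, in the layout of the MACS peak caller, with 117450 peaks for DMSO, 90600 for E2 and 104582 for FULV. The peak names say that replicates were pooled before calling, and gaps in their numbering show that the lists were then reduced by a rule not given in the sources used here. The fold column of these deposited lists is the authors' enrichment of a peak over its local background, with medians of 7.52, 6.15 and 9.36 for DMSO, E2 and FULV. The −log10 q column of these lists is the authors' value for each peak. A column of −log10 p was not used here. The score column deposited by the authors equals 10 times the −log10 q without its decimals. Score and fold were used only to describe or rank peaks within a list. All 123459 regions of the count table were identical to the regions that result from merging the 3 lists, with the start of the table read as counted from 0. Positions are given counted from 1 in hg38.

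Total counts ran from 5223188 to 13826806 per library. Regions were kept where edgeR's filter by group found enough counts, which left 120680 regions and removed 2779. Each comparison was tested per region with edgeR's quasi-likelihood F-test (version 4.0.16, R 4.3.3, limma 3.58.1) with TMM factors, in 1 fit over all 9 libraries with the group as its term. A region was called at a Benjamini-Hochberg adjusted p under 0.05, and all values after ± are SD over 3 libraries unless named as a standard error. Fold changes are fitted values on the log2 scale. Levels are given as CPM, the counts scaled to a common library size by total count and TMM factor.

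The reference at hand gave gene starts and ends (GRCh38.p14, the assembly of hg38) without strand, transcripts or sequence. Each region was therefore assigned to the nearest of 19974 protein-coding genes, measured from the middle of the region to the gene's span, up to 100000 bp, in place of the nearest transcription start. A gene was found for 108929 regions (88.2%). Location was tested as lying within 1000 bp of either end of a protein-coding gene, with Fisher's exact test, two-sided, against tested regions not called. The planned searches for sequence motifs and the planned GC correction need a genome sequence and were not run.

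The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. For each comparison the rule named the 10 regions with the largest rise and the 10 with the largest fall among called regions whose 3 libraries of 1 group all lay above the 3 of the other, 1 region per gene. It also named 21 fixed genes, each by its called region with the largest change or, with none called, by the region nearest to a gene end. The 12 gene lists were estrogen-induced, estrogen-repressed, luminal identity, basal and mesenchymal, leukocyte, fibroblast and endothelial, immediate early, aryl hydrocarbon receptor, glucocorticoid and progesterone, cell cycle, coactivators and corepressors, and housekeeping genes. Leukocyte, fibroblast and endothelial lists stood for other cell types. Lists were tested with limma's camera at a preset correlation of 0.01 and at an estimated one, and with fry, adjusted over the 12 lists of a comparison. Of the estrogen-induced genes with a match, 7 were also in another list, and of the immediate early genes 4.

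E2 and FULV were compared with the same DMSO libraries. The correlation, covariance and overlap of both comparisons were therefore set beside 20 simulations with no effects and 20 with the fitted E2 effects and FULV unchanged, drawn with the fitted spread. Each region was drawn independently, so differences between libraries that are shared across regions were left out. The 3 DMSO libraries cannot be divided into parts of at least 2. Principal components were taken from log2 CPM.

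The tests were tried on simulated counts drawn with the real means and library sizes, in which for E2 100 tested regions were changed by log2 0.5 and 99 by log2 1, with 99 and 100 others for FULV. With the spread estimated per region, edgeR recovered 45.5% of regions changed by log2 1 and 1% of those changed by log2 0.5 in the simulated E2 comparison, and 32.4% of its calls were false (120460 regions). The simulated FULV comparison gave 55% and 5.1% with 25.9% false calls, and the simulated difference between FULV and E2 gave 55.8% and 5.5% with 20.8% false calls. With a spread that followed the mean smoothly, tried after that result was seen, the recovered shares were 52.5% and 6% for E2 with 6.5% false calls (120420 regions). They were 68.7% and 3% for FULV with 4.1% false calls, and 62.1% and 5% for FULV and E2 with 2.2% false calls. In the list test, 1 list raised by log2 0.3 was called and 0 of the 11 others.

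Alternatives were DESeq2 (version 1.42.0), total counts without factors, RLE factors, offsets that follow abundance (loess span 0.3), no filter, a mean count of at least 50, only the compared groups in the fit, the replicate number as a block, each library left out in turn, a gene distance of 20000 bp, a gene end distance of 3000 bp, a reciprocal peak overlap of 50% and the peaks above the median score of each list. Thinning of every library to 5223188 counts, robust spread estimates and 1 surrogate variable from sva (version 3.50.0) were added after seeing the data. Peak lists were compared by an overlap of at least 1 bp. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and figures drawn with matplotlib 3.10.9.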

Results

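ATAC-seq counts were available for 9 libraries of MCF-7 cells, 3 each after 45 min with DMSO, with 1 nM E2, the natural ligand of the estrogen receptor, and with 100 nM FULV, an antagonist that leads to breakdown of the receptor and differs from estradiol by a long side chain on its B ring. The counts covered 123459 regions. Total counts were 5223188, 13826806 and 13008539 in DMSO replicates 1, 2 and 3. They were 6062313, 7461747 and 11414673 in E2 replicates 1, 2 and 3 and 8177075, 11124658 and 7035030 in FULV replicates 1, 2 and 3. Pairs of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom from 1.09 (DMSO replicates 2 and 3) to 3.06 (DMSO replicates 1 and 2), so each was kept as its own sample. DMSO replicate 1 stood apart, with a mean correlation across regions of 0.926 with its group against 0.947 to 0.962 in the other 8 libraries.

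**Figure D1:**
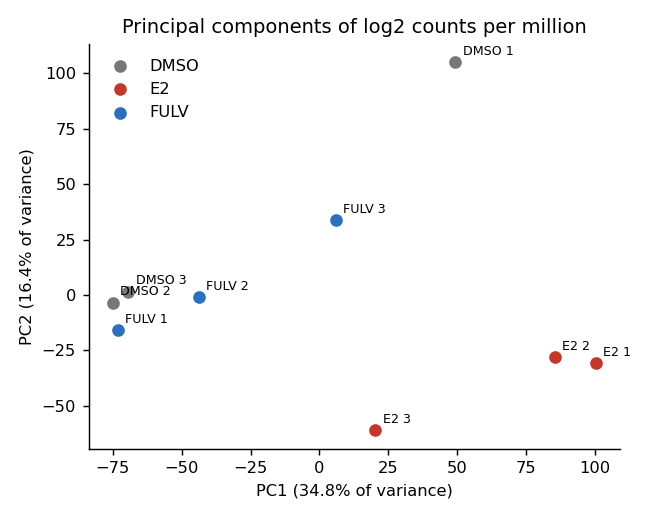
The 9 libraries on the first and second principal components of log2 CPM, which hold 34.8% and 16.4% of the variance, coloured by group. DMSO replicate 1 lies at 105 on the second component, away from DMSO replicates 2 and 3, and at 49.3 on the first, within the 20.3 to 100.3 of the E2 libraries.

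The first comparison asked which regions changed accessibility with estradiol. Regions near classical estrogen receptor target genes rose within 45 min. Near TFF1, which codes for a secreted trefoil peptide, a region on chromosome 21 (42361122 to 42361557, 943 bp outside the gene) went from 4.67 ± 1.82 CPM (counts scaled to a common library size) with DMSO to 20.7 ± 4.72 with E2 (SD, n = 3), 4.88-fold. A region inside GREB1, an estrogen receptor cofactor (chromosome 2, 11524218 to 11524872), went from 3.17 ± 0.834 to 18.9 ± 1.73 CPM, 6.38-fold. Regions near FOSB and NR4A2, immediate early transcription factors, fell, to 0.323 and 0.354 of their DMSO levels.

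In all, 5696 of 120680 tested regions were called, 4350 higher and 1346 lower with E2 (76.4% higher). Among them 2211 rose and 89 fell by at least log2 1, with medians of 1.01 and −0.61 over the called regions. The groups were fully separated in 19.2% of tested regions, where chance gives 10%. The counts depended on single libraries. Without DMSO replicate 1 there were 12112 calls (8512 higher, 3600 lower), without DMSO replicate 2 there were 3150 (2651 and 499), without DMSO replicate 3 there were 2979 (2488 and 491), without E2 replicate 1 there were 3669 (3149 and 520), and without E2 replicate 2 the lower calls numbered 813. DESeq2 called 3640 regions.

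**Figure D2:**
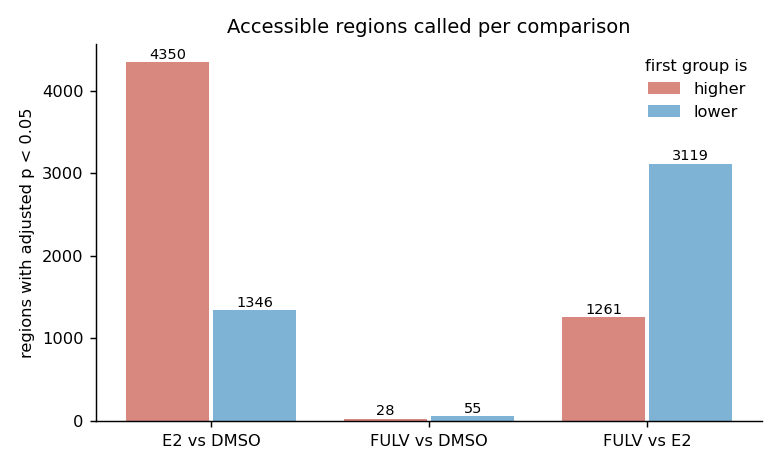
Number of regions with an adjusted p under 0.05 in each comparison of 3 against 3 libraries, split by direction of the first-named group. E2 vs DMSO had 4350 higher and 1346 lower regions, FULV vs DMSO 28 and 55, and FULV vs E2 1261 and 3119.

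Estrogen-induced genes moved as a group. Of 579 regions assigned to this list, 136 were higher with E2 and 0 lower in edgeR's test, against 184 higher and 2 lower when adjusted over the list alone. At an unadjusted p under 0.05 the list had 229 higher and 9 lower regions, and DESeq2 called 105 higher and 0 lower. The higher regions belonged to 42 of 48 genes. The camera test gave an adjusted p = 1.79e-26, and adjusted p = 0.00589 with an estimated correlation, and fry gave an adjusted p of 0.000147. DMSO replicate 1 lay 0.04 log2 above the other DMSO libraries over this list, and the E2 libraries lay 0.40 to 0.44 above them.

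Among its members, PGR, the progesterone receptor gene, had 4 of 10 regions higher, the largest from 4.48 ± 0.563 to 18.9 ± 2.39 CPM (chromosome 11, 101033986 to 101034534, inside the gene). IGFBP4, a binding protein of insulin-like growth factors, had 4 of 7 higher, up to log2 2.69 (standard error 0.22, adjusted p = 1.3e-07). CTSD, the protease cathepsin D, had 6 of 10 higher, up to log2 2.32. CCND1, cyclin D1, had 3 of 12, the largest 99289 bp from the gene (log2 2.45). NRIP1, a receptor corepressor, had 4 of 31, up to log2 2.33, and RET, a receptor kinase, 6 of 10, up to log2 2.30. TFF1 itself had 4 of 5 regions higher and GREB1 16 of 30. MYC had 8 of 28 higher, up to log2 1.44, XBP1 5 of 15, SIAH2 2 of 17, CA12 3 of 18 and RARA 2 of 15. The RARA region (log2 1.46) was not called without DMSO replicate 2, DMSO replicate 3 or E2 replicate 3, with an adjusted p of up to 0.152.

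**Figure D3:**
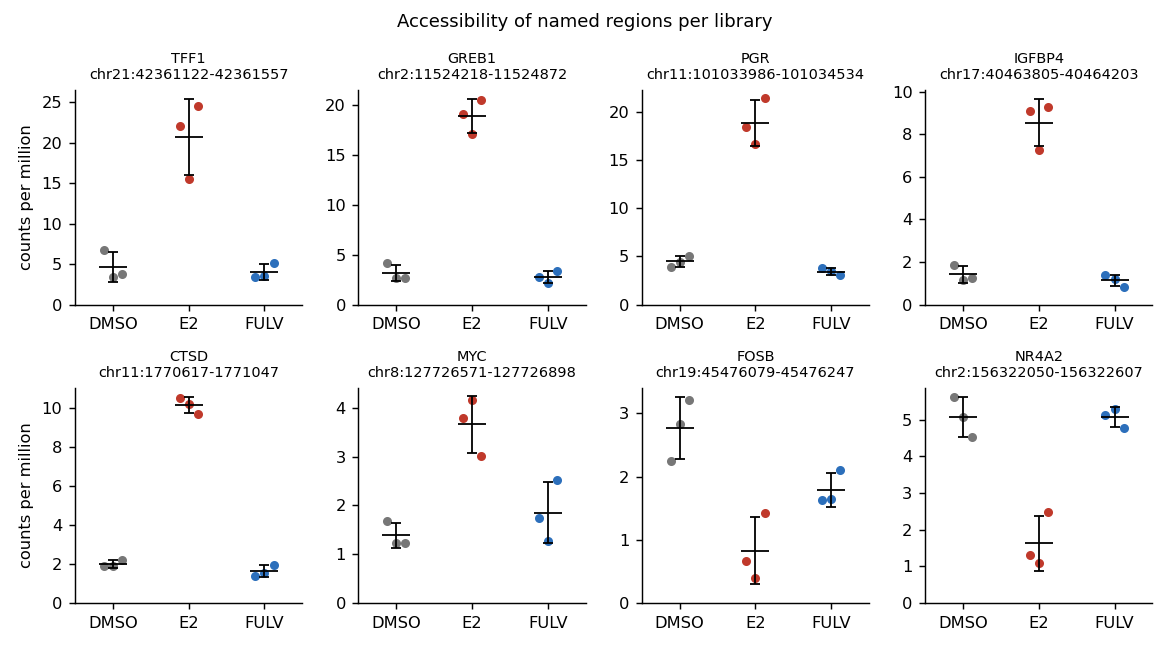
CPM of 8 regions per library (points), with the group mean and SD as bars (n = 3), by treatment. E2 libraries lie above DMSO and FULV libraries near TFF1, GREB1, PGR, IGFBP4, CTSD and MYC and below them near FOSB and NR4A2.

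The 10 largest rises by fold lay in or near MECOM, SSR3, MCF2L, FARP1, SLC1A2, ELAPOR1, CD276, SPEG, NHLRC2 and ZIM2, from log2 3.23 in MECOM, a zinc finger transcription factor, to 2.88 at ZIM2. The MECOM region (chromosome 3, 169623830 to 169624419) went from 1.85 ± 0.355 to 16.5 ± 1.15 CPM, and the one in MCF2L, an exchange factor of Rho proteins (chromosome 13, 112913289 to 112913950), from 2.52 ± 0.346 to 21.9 ± 1.31. All 10 stayed called with any 1 library left out. DMSO counts per library were only 1 to 8 at SSR3, 1 to 7 at SLC1A2 and 1 to 5 at ZIM2, so the size of these folds is uncertain. The falls were smaller, from log2 −1.80 at ZNRF3, an inhibitor of Wnt signalling, to −1.37 at PNPT1, with GAREM1, CKAP4, FOSB, FAF1, NR4A2, UNC80, GNG12 and PDK1 between them. Only FOSB (adjusted p = 0.00603) and NR4A2 (adjusted p = 0.000581) of these 10 stayed called with every library left out in turn. The other 8 lost their call without at least 1 of DMSO replicates 2 and 3, E2 replicates 1, 2 and 3 and FULV replicate 1, with highest adjusted p-values from 0.0506 at PNPT1 to 0.212 at PDK1.

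Immediate early genes went both ways. Of 316 regions, 19 were higher (7 genes) and 23 lower (10 genes), or 27 and 32 adjusted over the list alone, and camera did not call the list (adjusted p = 0.314). NR4A1 and NR4A2, orphan nuclear receptors, each had 5 lower regions, of 13 and 10, with largest falls of log2 −1.03 and −1.50. DUSP1, a phosphatase of MAP kinases, had 4 of 16 lower (log2 −1.23), and FOSB, JUN, JUNB, JUND, IER2, MCL1 and BTG2 also had lower regions. Higher regions lay at KLF4 (log2 2.03), EGR2 (1.60), MYC, IER5 (1.36), FOS (1.07), IER3 (1.00) and EGR3 (0.66). The higher regions of MYC (8) and EGR3 (1) were also counted in the estrogen-induced list, and the lower ones of BTG2 (2) in the estrogen-repressed list. Of the 181 regions within 20000 bp, 8 were higher and 21 lower with a median of −0.15, and camera called that set lower (adjusted p = 0.000922), a call that was lost at adjusted p = 0.417 with an estimated correlation (unadjusted p = 0.174).

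Luminal identity genes had 21 of 296 regions higher and 11 lower (24 and 16 adjusted over the list alone). GRHL2, an epithelial transcription factor, had 6 of 35 higher, up to log2 1.81. The keratin genes KRT8 and KRT18 had 3 of 16 and 2 of 9 regions lower, at −0.56 ± 0.09 (standard error, adjusted p = 0.000327) and −0.69 ± 0.17 (adjusted p = 0.0232). The KRT18 call was lost without DMSO replicate 2 or 3 or E2 replicate 1 or 2 (adjusted p up to 0.142). ESR1, the estrogen receptor gene, had 3 of 46 higher and 1 lower, and its region with the largest change (log2 0.78) stayed called only without DMSO replicate 1 or FULV replicate 3, with an adjusted p of up to 0.28 without any 1 of the other 7 libraries. GATA3 had 1 higher and 1 lower of 23, the latter at log2 −0.75 and lost without DMSO replicate 2 or E2 replicate 1 (adjusted p up to 0.0703). FOXA1, a pioneer factor, had 0 of 7 called by edgeR and DESeq2, with 1 lower at an unadjusted p under 0.05, and the region at its end, log2 −0.34, was called lower without DMSO replicate 1 (adjusted p = 0.0422).

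Of the remaining lists, estrogen-repressed genes had 4 of 150 regions higher and 7 lower (4 and 8 adjusted over the list alone). The lower ones lay at ERBB2, EFNA1, IL1R1, BTG2 and SMAD6 and the higher ones at SEMA3B and IRS2. The fry test called this list lower (adjusted p = 0.0108) and camera did not (adjusted p = 0.101, and adjusted p = 0.0557 with an estimated correlation). Basal and mesenchymal genes had 10 higher and 1 lower of 157, coactivators and corepressors 12 and 4 of 263, and cell cycle genes 6 and 1, among them CCND1 and MKI67. Targets of the glucocorticoid and progesterone receptors had 4 and 5 of 138, aryl hydrocarbon receptor targets 1 and 1 of 49 and housekeeping genes 5 and 2 of 98. Adjusted over the list alone these counts were 10 and 3, 12 and 6, 7 and 1, 4 and 7, 1 and 1, and 5 and 2. FKBP5 had 0 of 13 called by edgeR and DESeq2 (2 higher at an unadjusted p under 0.05), and CYP1A1 0 of 3 (1 higher). Fibroblast and endothelial genes had 1 higher and 0 lower of 100 regions, and 0 adjusted over the list alone. Leukocyte genes had 0 of 31 called by edgeR and DESeq2, with 1 higher and 2 lower at an unadjusted p under 0.05. Camera called none of these lists (adjusted p from 0.101 to 0.919). In the luminal, fibroblast and endothelial, aryl hydrocarbon receptor and cell cycle lists the median change was below 0, as was camera's direction, and the mean above 0.

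Regions that rose with E2 lay away from gene ends. Within 1000 bp of an end were 3.6% of them against 13.9% of regions not called (odds ratio 0.234, 95% interval 0.198 to 0.274, Fisher's exact test, adjusted p = 7.02e-111). Regions that fell were near gene ends in 12.3% (odds ratio 0.866, 0.731 to 1.02, adjusted p = 0.132). Within 20 classes of accessibility the odds ratios were 0.188 and, for regions that fell, 0.499 (adjusted p = 3.94e-151 and 2e-18). Regions are not independent replicates, so these tests describe the called regions. The E2 libraries had 44.2, 44.5 and 45.9% of their counts in the 10% most accessible regions, against 44.5, 47 and 46.3% in DMSO replicates 1, 2 and 3 and 45.7 to 47.6% in the FULV libraries, so a part of weaker signal over background with E2 in the E2 calls and their location was not excluded.

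The second comparison asked what FULV did to the same hormone-deprived cells. Accessibility fell below the DMSO level at regions in or near ATRNL1, SHANK2, CYP2A7 and HERC6, and these 4 stayed called with any 1 library left out and under every other setting. The region in ATRNL1 (chromosome 10, 115664756 to 115665203) went from 8.03 ± 0.895 to 1.70 ± 0.262 CPM, log2 −2.22 (standard error 0.21, adjusted p = 6.1e-05). The region in SHANK2, a synaptic scaffold gene (chromosome 11, 70805211 to 70806376), went from 43.8 ± 2.14 to 17.0 ± 2.49. The region 39135 bp from CYP2A7 (chromosome 19, 40920849 to 40921884) went from 65.3 ± 3.90 to 23.9 ± 0.903, and that 43549 bp from HERC6 (chromosome 4, 88334945 to 88335662) from 50.2 ± 2.15 to 23.3 ± 1.16.

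In all 83 regions were called, 28 higher and 55 lower, with medians of log2 0.86 and −0.92, and 12.7% of tested regions had separated groups against 10% by chance. The higher and lower counts were 0 and 5 without FULV replicate 2, 117 and 186 without DMSO replicate 1, 2 and 14 without DMSO replicate 2 and also without DMSO replicate 3, 1 and 15 without FULV replicate 1, 11 and 24 without E2 replicate 1 and 9 and 18 without FULV replicate 3. It was 37 with only the compared groups in the fit, 26 after thinning, 172 with robust spread estimates (48.8% higher) and 986 with 1 surrogate variable (56.5% higher, against 33.7%), so no single count stands for the FULV response.

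The other named falls were at CARM1, a coactivator of nuclear receptors (log2 −1.66), C2, PAM, MAPKAP1 (−1.22), RUBCNL (−1.12), NAALADL2 and, among the fixed genes, GREB1 (3 of 30 lower, −0.83), NRIP1 (1 of 31, −1.04) and CTSD (1 of 10, −0.48). Rises were at SPATA13 (log2 1.40), HS6ST1, SUGP2, ARRB1, WWC1, KCNK6, RBM5, GNA12, PKP3 and SERPINA1 (0.94). Each of these lost its call without FULV replicate 2, those of MAPKAP1, GREB1 and WWC1 (adjusted p = 0.0617 for each) only then. The others lost it also without at least 1 of DMSO replicates 2 and 3, E2 replicates 1, 2 and 3 and FULV replicates 1 and 3, with adjusted p-values up to 0.627 at CARM1 without DMSO replicate 3. The WWC1 region (chromosome 5, 168316024 to 168316762) stood at 10.1 ± 0.843 CPM with DMSO, 21.5 ± 2.85 with FULV and 37.3 ± 4.40 with E2.

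Of the estrogen-induced list, 2 regions were higher with FULV, at WWC1 and NHERF1, and 6 lower, at GREB1, CTSD, NRIP1 and SGK3, and 6 and 15 adjusted over the list alone. At an unadjusted p under 0.05 this list had 26 higher and 52 lower regions, and DESeq2 called 2 higher and 9 lower. Camera did not call the list (adjusted p = 0.783). The coactivators and corepressors had 2 lower regions of 263, at CARM1 and NRIP1 (1 higher and 2 lower adjusted over the list alone). The other 10 lists had 0 regions called by edgeR. At an unadjusted p under 0.05 these lists had from 2 regions (leukocyte genes) to 27 (luminal identity genes), and DESeq2 called 1 lower region each in the luminal identity and immediate early lists. Adjusted over the list alone, 1 higher and 1 lower luminal identity region, 1 lower immediate early region and 1 higher region of the glucocorticoid and progesterone list passed. Camera called no list (adjusted p from 0.783 to 0.92). The median, the mean and the direction of the test differed in sign in the basal and mesenchymal, leukocyte, immediate early, coactivator and corepressor, and housekeeping lists. Of the fixed genes, TFF1, PGR, MYC, CCND1, SIAH2, CA12, RET, IGFBP4, ESR1, GATA3, KRT8, FOXA1, CYP1A1 and FKBP5 had no region called by either tool, with 0 to 4 regions per gene at an unadjusted p under 0.05. XBP1, RARA, KRT18 and FOS had none by edgeR and 1 lower each by DESeq2, with 3 to 7 lower at an unadjusted p under 0.05.

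Near gene ends lay 21.4% of higher and 5.5% of lower regions, against 13.5% of those not called (odds ratios 1.75 and 0.369, adjusted p = 0.261 and 0.132 by Fisher's exact test). Within 3000 bp the odds ratio of the lower regions was 0.376 (adjusted p = 0.0453), and within classes of accessibility it was 0.198 (adjusted p = 0.00166).

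The third comparison set FULV against E2, related molecules given for the same 45 min at different doses, 100 nM and 1 nM. Estrogen receptor target genes were less accessible with FULV. IGFBP4 had the largest difference, 6.79 ± 1.07 CPM with E2 and 0.654 ± 0.372 with FULV (log2 −3.37, 95% interval −4.02 to −2.73). GREB1 stood at 48.3 ± 4.06 and 5.07 ± 0.627 (log2 −3.24, −3.53 to −2.95), and TFF1 at 6.28 ± 0.476 and 0.869 ± 0.484 (log2 −2.95, −3.57 to −2.32). Regions at the immediate early genes NR4A2, DUSP1 and NR4A1 were more accessible with FULV than with E2, by log2 1.53, 1.27 and 1.19. Against DMSO these changed by log2 0.03, 0.04 and 0.16 with FULV (not called) and by −1.50, −1.23 and −1.03 with E2. The IGFBP4, GREB1 and TFF1 regions were also not called for FULV vs DMSO (log2 −0.93, −0.76 and −0.89). With E2 they rose by log2 2.44, 2.48 and 2.06 over DMSO, so the differences lay mainly in the E2 change.

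There were 4380 called regions, 1261 higher and 3119 lower with FULV, of which 60 and 1704 differed by at least log2 1, and 19.5% of tested regions had separated groups against 10% by chance. The count was 2827 without E2 replicate 1 (505 higher, 2322 lower), 2702 without FULV replicate 1 (501 and 2201) and 2398 without FULV replicate 2 (495 and 1903), and the higher calls numbered 669 without E2 replicate 2 and 2064 without DMSO replicate 1.

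Of the 579 estrogen-induced regions 120 were lower with FULV and 1 higher (175 and 1 adjusted over the list alone). They covered 41 of 48 genes (camera adjusted p = 2.47e-33, and adjusted p = 0.00237 with an estimated correlation). GREB1 had 20 of 30 lower, CTSD 7 of 10, NRIP1 6 of 31, XBP1 and MYC 5 each, TFF1, PGR and IGFBP4 4 each, and CCND1, CA12, SIAH2 and RARA 2 each. RET had 4 of 10 lower, and its largest difference (log2 −1.92) was not called without E2 replicate 1 or 2 or FULV replicate 1 or 2 (adjusted p up to 0.225). STC2, a secreted glycoprotein hormone, and FHL2 had falls of up to log2 −2.75 and −1.83. The other large falls lay at IFITM10, PDLIM3, VPS13B, MAPKAP1, MECOM, MCF2L and RREB1, from log2 −3.36 to −2.86, and all stayed called with any 1 library left out. FULV counts per library were only 1 to 3 at PDLIM3 and 1 to 2 at VPS13B, so the size of these falls is uncertain. The rises were at SLAIN1 (log2 1.72), ARPC1B, PLK2, SYDE2, TRIQK, SEMA3E and EIF4G3 as well as the immediate early genes. TRIQK, NR4A1, NR4A2 and DUSP1 stayed called with any 1 library left out. The other 6 lost the call without at least 1 of E2 replicates 1, 2 and 3 or FULV replicates 1 and 2 (adjusted p up to 0.142), SLAIN1 without E2 replicate 2 (adjusted p = 0.0582).

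Immediate early genes had 22 regions higher and 16 lower with FULV (29 and 26 adjusted over the list alone), and estrogen-repressed genes 9 and 4 (12 and 4), the former at ERBB2, EFNA1, BTG2, BMF and SMAD6. Luminal identity genes had 13 and 11 (13 and 11), with KRT8 higher in 3 of 16 (log2 0.51, 95% interval 0.33 to 0.70) KRT18 lower in 1 of 9 (−0.50), and GATA3 and ESR1 differing by up to log2 −1.07 and −0.84. Basal and mesenchymal genes had 2 and 6 (2 and 6), aryl hydrocarbon receptor targets 2 and 1 (3 and 1), glucocorticoid and progesterone targets 7 and 1 (9 and 3), cell cycle genes 0 and 3 (0 and 3), coactivators and corepressors 5 and 9 (6 and 10), and housekeeping genes 3 and 4 (7 and 4). Leukocyte and fibroblast and endothelial genes had 0 of 31 and 0 of 100 called by edgeR and DESeq2, with 5 and 8 at an unadjusted p under 0.05. Camera called no list but the estrogen-induced one (adjusted p from 0.119 to 0.83), and fry also the estrogen-repressed one (adjusted p = 0.0271). Within 20000 bp camera also called the immediate early (adjusted p = 0.00432), glucocorticoid and progesterone (adjusted p = 0.00964) and estrogen-repressed lists (adjusted p = 0.029) higher with FULV. None of these 3 calls held, at adjusted p = 0.493, 0.278 and 0.0556 with an estimated correlation. The medians of the luminal and of the fibroblast and endothelial lists lay above 0 and their means below 0. FOXA1 (log2 0.21, 95% interval −0.15 to 0.57), CYP1A1 (0.12, −0.19 to 0.43) and FKBP5 (−0.31, −0.91 to 0.29) had no region called by edgeR or DESeq2, with 1 region each at an unadjusted p under 0.05. Each interval is for the 1 region at the gene's end only, so it does not limit changes in the gene's other regions.

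Both directions lay away from gene ends, with 3.5% of lower regions (odds ratio 0.225, 95% interval 0.184 to 0.273, adjusted p = 9.42e-83) and 6.8% of higher ones (0.455, 0.361 to 0.568, adjusted p = 1.07e-14) against 13.8% of regions not called, by Fisher's exact test. Within classes of accessibility the odds ratios were 0.174 and 0.224.

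The last comparison asked how FULV acted at the regions that E2 changed. At the 4350 regions higher with E2 the median FULV change against DMSO was log2 0.19 (quartiles 0 and 0.40) and was above 0 in 74.9%. Fitted on regions with a mean count of at least 50, it was 0.128 over the 3099 called higher in that fit. Of the 4350 regions FULV was called below E2 in 2639 (60.7%) by edgeR and 1994 by DESeq2, and above E2 in 0. The regions were chosen in the same E2 libraries. Simulations with only E2 effects and FULV equal to DMSO gave 90.1% below E2 (89.2 to 91.4%) and a mean of 0.2 regions above it. FULV below E2 is therefore no sign of an action of FULV. The observed 60.7% lay under that range, and the median difference from E2 was smaller (log2 −0.83, against −1.08 to −1.05 simulated). The simulations left out differences between libraries that are shared across regions, so this departure does not decide whether FULV acted. A set of 38 fell below DMSO with FULV, among them 3 regions in GREB1, a region in JAK1, a cytokine receptor kinase (log2 1.46 with E2 and −0.96 with FULV), regions in SHANK2 and SGK3 and one near CLIC6, with median levels of 18.8 CPM with DMSO, 35.7 with E2 and 10.1 with FULV. Another 26 were higher with both, among them WWC1, NHERF1, KCNK6 and SERPINA1, at medians of 7.65, 25.7 and 13.8, and FULV lay below E2 in 19 of these. JAK1 and CLIC6 were chosen after their values were seen. Both sets depended on single libraries: the 26 and 38 regions became 0 and 2 without FULV replicate 2, 1 and 12 without FULV replicate 1, 9 and 12 without FULV replicate 3, 2 and 7 without DMSO replicate 2, 2 and 9 without DMSO replicate 3, 11 and 15 without E2 replicate 1, 17 and 28 without E2 replicate 2, and 100 and 58 without DMSO replicate 1.

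At the 1346 regions lower with E2 the median FULV change was −0.07, close to the −0.0659 simulated with only E2 effects. In other settings the median was taken over regions called lower in that setting. Its shifts there can come from the regions as well as from FULV. It was −0.121 with abundance-trended offsets (1552 regions), against −0.0819 simulated with them. It was −0.041 with DESeq2 (826), −0.183 without DMSO replicate 1 (3600), −0.129 without E2 replicate 2 (813) and −0.021 without FULV replicate 3 (1308). At the 1346 regions FULV was called above E2 in 697 (51.8%) by edgeR and 558 by DESeq2. It was below E2 in 0 by either tool, with 1 below at an unadjusted p under 0.05. The simulations with only E2 effects gave 65.7% above E2 and a mean of 0.15 regions below it. The overlap of regions higher with both was 26 where independent lists give 1.01, simulations with no effects 0.65 and simulations with only E2 effects 2.4. Regions lower with both numbered 3, against 0.613 and 2.2 with only E2 effects, and 94 without DMSO replicate 1. For regions higher with E2 and lower with FULV the observed 38 stood against 1.98 from independent lists and 0 in simulations with only E2 effects. Those simulations called a mean of only 5.4 regions higher and 5.65 lower with FULV, against 28 and 55 observed. These overlaps therefore come from lists of unlike size. Shared DMSO libraries also move both changes the same way, so opposite calls could hardly arise in the simulations. The log2 fold changes of the comparisons correlated at 0.413 across regions, which are not independent replicates, against 0.464 simulated for no effects and 0.333 for only E2 effects. Their covariance was 0.0439 against 0.0281 in either simulation, a difference of 0.0158. Among regions with a mean count of at least 50 it was 0.0202, against 0.0145 simulated for those regions. Part of any excess may come from the shared DMSO libraries, and the simulations left out differences between libraries that are shared across regions. Without DMSO replicate 1 the covariance was 0.0864, against 0.0309 simulated for that design. The median FULV change at the 8512 regions called higher with E2 in that fit was 0.367, against 0.0223 simulated with only E2 effects.

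**Figure D4:**
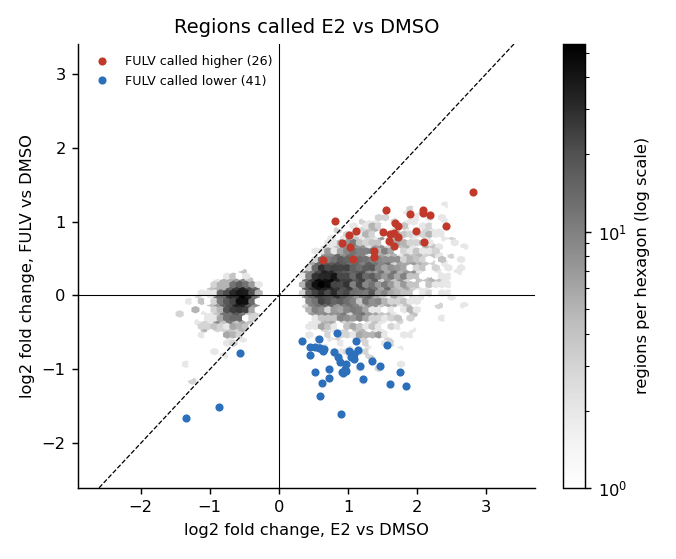
Fitted log2 fold change of FULV vs DMSO against that of E2 vs DMSO at the 5696 regions called for E2, with shading for regions per hexagon on a log scale and a dashed line for equal changes. Red points are the 26 regions called higher and blue points the 41 called lower with FULV, and most of the 4350 regions higher with E2 lie below the dashed line.

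The deposited peak lists held 117450 peaks for DMSO, 90600 for E2 and 104582 for FULV. The shares that overlapped differ with these lengths, since 86315 E2 peaks overlapped a DMSO peak and 84746 DMSO peaks an E2 peak, and 84906 E2 peaks overlapped a FULV peak and 82599 FULV peaks an E2 peak. Of the E2 peaks 95.27% overlapped a DMSO peak and 93.72% a FULV peak, while 72.15% of the DMSO peaks and 78.98% of the FULV peaks overlapped an E2 peak. DMSO and FULV peaks overlapped by 85.78% and 94.93%. Of the merged regions 80909 (65.54%) came from all 3 lists, 14124 from DMSO alone, 4179 from FULV alone and 3115 from E2 alone. Regions of the E2 list alone had a median E2 change of log2 0.98, and 806 of 2980 tested were called higher, while 0.51% of those of the DMSO list alone were called for E2. Regions of the FULV list alone had a median FULV change of 0.40 with 2 of 3809 called. The lists hold 1 pooled call per condition and so have no replicate error. They were called from the pooled replicates of the same conditions as the counts. Regions of 1 list alone were thus partly chosen for a higher level in that condition, and their changes give no separate support.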

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

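The DESeq2, total count, RLE, trended offset, filter (among them a mean count of at least 50), compared groups only, replicate block and left-out library settings were planned for the region counts. For the covariance only the total count, trended offset, replicate block and left-out library settings were planned. Thinning, robust spread estimates, 1 surrogate variable, DESeq2, RLE and the filters for the covariance, the settings for the estrogen-induced counts, for the overlaps of E2 and FULV calls and for the FULV change in E2 regions, the estimated correlation within 20000 bp and the classes of accessibility were chosen after the data were seen. The planned sequence motif tests and GC corrections, alone and with the replicate block, were not run for lack of a genome sequence. No region called both as reported and in another setting changed sign, but the larger direction of FULV vs DMSO turned, from 33.7% higher to 56.5% higher with 1 surrogate variable. Within 20000 bp the camera direction turned for lists not called: estrogen-repressed in FULV vs DMSO, and aryl hydrocarbon receptor and cell cycle in FULV vs E2. The E2 vs DMSO count of 5696 was 3640 with DESeq2 and 3380 with thinning, and 2979 to 12112 with 1 library left out. The FULV vs DMSO count of 83 was 24 with a replicate block, 26 with thinning, 37 with the compared groups only, 172 with robust spread estimates and 986 with 1 surrogate variable, whose estimation from the same counts makes its p-values too small, and 5 to 303 with 1 library left out. The FULV vs E2 count of 4380 was 2398 to 6443 with 1 library left out. With the replicate block the counts were 4673, 24 and 3543, but the replicate numbers were not used as pairs: after removing group means, correlations ran from −0.26 to 0.23 between libraries of the same number and from −0.35 to 0.33 between others. The best match in another group had the same number in 4 of 18 cases, where chance gives 6. With the replicate block fry called basal and mesenchymal genes for E2 vs DMSO (adjusted p = 0.00693) and FULV vs E2 (adjusted p = 0.00392) and no longer estrogen-repressed genes for FULV vs E2 (adjusted p = 0.0501). The covariance of 0.0439 was 0.0202 with a mean count of at least 50 and 0.0336 to 0.0864 with 1 library left out. The lists called within 20000 bp numbered 2 for E2 vs DMSO (immediate early added) and 4 for FULV vs E2 (immediate early, glucocorticoid and progesterone, and estrogen-repressed added), against 1 each, and with an estimated correlation again 1 each. Within 3000 bp the FULV vs DMSO lower odds ratio was 0.376. Within classes of accessibility it was 0.198, and that of E2 vs DMSO lower was 0.499. With a reciprocal overlap of 50% the peak overlaps were 68.05% of DMSO in E2, 81.73% of DMSO in FULV, 88.22% of E2 in DMSO, 84.37% of E2 in FULV, 91.78% of FULV in DMSO and 73.09% of FULV in E2. Among peaks above the median score they were 74.25%, 87.11%, 97.09%, 95.3%, 96.98% and 81.24%, in that order. Stricter overlap lowers a share by construction. For the other changes the cause was not tested. The 26 regions higher with E2 and FULV ranged from 0 to 100 with 1 library left out and from 5 to 262 in the other settings, and the 38 higher with E2 and lower with FULV from 2 to 58 and from 13 to 125. Over all settings the estrogen-induced regions numbered 97 to 158 higher with E2 and 92 to 142 lower with FULV than with E2. Of the values of named regions under other settings, 2106 kept their side of the threshold and 222 lost the call. Another 2 gained it (FOXA1 for E2 vs DMSO without DMSO replicate 1, FOS for FULV vs DMSO with 1 surrogate variable). Of the values called as reported or in the other setting, 0 changed sign. For regions called in neither, the sign was not compared. At most 6% of simulated changes of log2 0.5 were called by edgeR. Depth was not varied in that test, so its part beside the spread and the 3 libraries per group was not separated.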

Other observations

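The counts of regions per gene, the estrogen-induced position of DMSO replicate 1, the depth and signal over background tests, the tests with a surrogate variable and the tests without DMSO replicate 1 were chosen after the result was seen. Regions that rose with E2 were clustered at genes. With at least 5 higher regions there were 85 genes, where random draws of as many regions gave a mean of 6.2 and at most 13 genes. These draws were not matched for accessibility or distance to gene ends, in which called regions differ. Neighbouring regions are also not independent, so the draws give no matched expectation. GSE1 had 18 of 74 regions higher, GREB1 16 of 30, TMEM164 13 of 25, and IGF1R, the receptor of insulin-like growth factor 1, 11 of 71. PREX1, an exchange factor of Rac, had 11 of 63, MLPH 9 of 19 and CXXC5 8 of 13. Genes with at least 5 lower regions numbered 12 (random mean 0.1), among them CDKN2B, an inhibitor of cyclin-dependent kinases, with 6 of 11 and TGFB2, a growth factor, with 5 of 20. FULV lay below E2 in at least 5 regions at 58 genes (random mean 1.6), with CLIC6 at 7 of 9 and SLC24A3 at 12 of 57. All of these genes but GREB1 were chosen after their values were seen.

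The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. For E2 vs DMSO the real split called 5696 regions and the highest other split 3102, and 136 and 3 regions of the estrogen-induced list. That other split set DMSO replicate 1 beside E2 replicates 1 and 2, which had the lowest total counts of these 6 libraries. For FULV vs E2 the real and the highest other split called 4380 and 0 regions, and 121 and 0 of the list. For FULV vs DMSO the real split called 83 and the highest other 597, with DMSO replicate 1 beside FULV replicates 2 and 3, so 2 of the 10 splits gave as many. For E2 vs DMSO and FULV vs E2, 1 of the 10, the real one, gave as many. A count several times the real one points to a structure of the samples.

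DMSO replicate 1 correlated less with its own group than any other library did. Its mean correlation was 0.926 with its own group and 0.93 with the other groups, and 0.912 and 0.923 after thinning. All other libraries correlated better with their own group than with the other groups. Shallow sequencing is argued against, since in 5 thinnings to its depth it stayed at least 0.0164 below the lowest of the others, and so is a DMSO label on an E2 library, since over the estrogen-induced list it lay 0.102 of the way from the other DMSO libraries to E2. In regions called higher with E2 without it that position was 0.552, above 0.5, but FULV replicate 3 also lay at 0.492, and its distance with trended offsets, 0.936 of the largest other, did not decide since it was not the largest before. Weaker signal over background may account for it: across the 9 libraries the leading within-group component fell with the share of counts in the 10% most accessible regions (r = −0.98, rho = −0.98, exact permutation p = 0.00463, adjusted over 2 relations 0.00926, r = −0.97 without the 2 farthest), and with log2 total counts (r = −0.91, rho = −0.95, p = 0.0231, r = −0.80 without the 2 farthest). The leading within-group component and the share came from the same counts, all within the deposited regions. Their relation is therefore no independent support, and the share leaves out reads outside those regions. The share of counts in a library's top 1000 regions hardly set DMSO replicate 1 apart. It was 11.67%, against 11.93% and 11.7% in DMSO replicates 2 and 3. No biological explanation was tested. The axis of that component lies along E2 vs DMSO once DMSO replicate 1 is left out. The 12112 regions called then are therefore no cleaner E2 result.

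FULV lay above DMSO in most regions higher with E2 (median log2 0.19), a candidate for weak opening by FULV. The estrogen-induced list as a whole showed no such opening. Over its 579 regions FULV replicates 1, 2 and 3 lay at −0.145, −0.076 and 0.002 of the way from DMSO replicates 2 and 3 to E2. Against a trend with accessibility or distance to gene ends, matched regions not called had 8% of that median. For the leading difference between libraries within groups, the median was 0.195 with 1 surrogate variable, or 0.173 at the regions called in that fit. The variable was 0.43, −0.38 and −0.33 in DMSO replicates 1, 2 and 3 and −0.40, −0.20 and 0.14 in FULV replicates 1, 2 and 3. These groups lay close on average, so fitting it could hardly move FULV against DMSO and does not decide. Lower quality of DMSO replicate 1 was not excluded. Without it and with 1 surrogate variable the median was 0.26 at the 3328 regions called higher there and 0.23 at the 4350 reported regions. The counts of DMSO replicate 1 were thus not needed for a positive median. That variable was estimated with DMSO replicate 1 included and followed the leading within-group component (r = 1). DMSO replicates 2 and 3 also served both to choose the regions and as FULV's control, so this fit does not decide. The fit without that variable (median 0.367) decides nothing either. In the regions called there the FULV libraries lay between DMSO and E2 in the order of their scores on that component. For FULV replicates 1, 2 and 3 the positions were 0.175, 0.295 and 0.492 and the scores −0.27, −0.08 and 0.35. Shared DMSO libraries stay open, since over 6 divisions of the DMSO libraries the lowest median was −0.26, with FULV compared with DMSO replicate 1 alone, while the other 5 ran from 0.114 to 0.187. With 1 surrogate variable the lowest was −0.119, which does not decide. Simulations with only E2 effects gave 0.0216 (0.014 to 0.0294), but they drew each region independently. In the real libraries the leading within-group component held 49.3% of the within-group variance over 47646 regions. The simulated range leaves out such shared differences, so FULV's weak opening remains a hypothesis.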
